A study of Mus musculus with 4 samples.

How the data were processed

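Hi-C was performed on CD8+ T cells sorted from the spleens of C57BL/6 mice, wild type (WT) or H1 cTKO;Vav-iCre (H1 cTKO). Hi-C ligates DNA ends that lie close together in the crosslinked nucleus, so that each sequenced pair of ends counts as 1 contact. H1 cTKO mice carry a conditional triple knockout of linker histone genes, and Vav-iCre is active in blood cells. The targeted genes are not given in the sources used here and are taken from knowledge of this mouse line as H1f2, H1f3 and H1f4. Per the labels, splenocytes from pairs of mice of each genotype were pooled, T cells were enriched by depletion on an affinity column, and CD8+ cells were purified by flow cytometry. Crosslinked cells were made into libraries with the Arima-HiC+ kit, which cuts with several restriction enzymes. The labels give 2 samples per genotype, 1 male and 1 female.

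The deposited files hold raw contact counts per pair of genomic bins, in 1 matrix per genotype at 100 kb and 1 at 25 kb, and the authors named them by genotype with no replicate. Each matrix was therefore taken as the pool of the 2 samples of its genotype. Per the submitters' processing notes, bcl2fastq 2.17 and HiC-Pro 2.11.3 were used and the genome build was mm10 (GRCm38.p6). Read filters and mapping settings are not given in the sources used here. The WT matrix held 170663481 contacts and the H1 cTKO matrix 183315791. The deposited bin tables of both genotypes were identical.

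No test across replicates was possible with 1 pooled matrix per genotype. Values carry counting error only, as 95% Wilson intervals for shares, 95% Poisson intervals for ratios of counts, or the SD over 20 Poisson resamples of each matrix. The labels name no molecular identifiers, and these intervals leave out the effects of amplification, animals and library preparation. No p-values were computed. The range over the 20 chromosomes (autosomes and X) is given as a description.

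For compartments, the 2% of 100 kb bins with the lowest coverage on each chromosome in either genotype were removed, which left 25048 bins. Each matrix was balanced by iterative correction (ICE, 60 iterations), leaving out contacts within a bin and between adjacent bins. Counts were divided by the mean at their distance, smoothed over 5% of the distance and capped at the 99.9th percentile. The first eigenvector of observed over expected minus 1 (E1) was computed per chromosome, scaled to a root mean square of 1 and signed so that bins with more protein-coding genes were positive (A), since no genome sequence was used. A bin was called switched when its sign differed between genotypes and the difference was over 3 combined counting SDs. Adjacent switched bins made a region if there were at least 2. Compartment strength was the mean of observed over expected within the highest 20% (AA) and within the lowest 20% (BB) of E1, divided by that between them (AB), with bins ranked on each genotype's own E1. Local contacts were the raw contacts of a 100 kb bin at 0.2 to 1 Mb as a share of its cis contacts of at least 0.2 Mb. Deciles of E1 were taken on the mean of both genotypes.

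Insulation was scored on 25 kb matrices balanced the same way (99894 bins kept), as the log2 of the mean contact count in a 250 kb diamond over the chromosome mean. Boundaries were local minima with a prominence over 0.2, and were shared when they lay within 1 bin. A first version of the score left pairs over 250 kb apart out of the diamond. It was replaced after its counts had been seen, because the standard diamond was the one fixed in advance, and it is kept as an alternative. The band of contacts within the same or an adjacent 100 kb bin is called under 0.2 Mb, and the next band accordingly began at 0.2 Mb.

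Genes were placed with the NCBI RefSeq table of GRCm38.p6, the build of the matrices. The table has no strand, so a gene was placed in the bin of its midpoint and not of its transcription start site, and coordinates are those of the table or of the bins. The 11 fixed lists (310 genes, of which Ahsp was not matched) and 9 lists defined by symbol were fixed before the data were examined. For each list the median E1 difference over its bins was set against 10000 random lists of gene-holding bins matched on decile of mean E1, and against 2000 circular shifts of the list along the chromosomes. The genes and regions named were the 10 regions with the largest mean E1 rise and the 10 with the largest fall, each with up to 3 protein-coding genes in alphabetical order. From each fixed list they were the 2 genes with the largest rise and the 2 with the largest fall, and from each list defined by symbol 1 of each. A few of the genes and regions that this rule takes are not reported here. Coverage of antigen receptor loci was the raw number of contact ends per 25 kb bin, without contacts inside the bin, relative to the chromosome median. All bins of a locus were used there, because the filter on low coverage removes deleted segments. This was changed after a filtered version had been seen.

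The switching rule and the boundary caller were tested on simulated data. With the sign of E1 reversed in 200 of 1875 bins of chromosome 1 (absolute E1 over 0.3), at the depths of both matrices, all 200 were called, with 0 calls elsewhere. These changes were large beside the median counting SD of the E1 difference (0.030), so smaller switches were not tested. In the real matrices, sign changes with an E1 difference over 0.5 numbered 549 from B to A and 89 from A to B, against 1069 and 413 called. Of 200 boundaries simulated on chromosome 19 (2458 bins) with contacts across them reduced to 0.4, all 200 were found, and 9 boundaries were called in a simulation without any. Weaker boundaries and uneven coverage were not simulated. In the real matrices, boundaries not shared between the genotypes had a median prominence of 0.425 in WT and 0.498 in H1 cTKO.

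The alternatives tried were fixed at the same time as the gene lists, except 6 added afterwards, and reuse the counting SDs of the 100 kb bins. They covered depth, bin filter, balancing, bin size, sex chromosomes, eigenvector matrix, E1 scale, thresholds, windows and denominators. The analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.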

Results

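Genome-wide contacts were measured by Hi-C in splenic CD8+ T cells of WT and H1 cTKO mice, to ask how loss of linker histone H1, which binds DNA between nucleosomes, changes active and repressed chromatin domains. Each genotype had 2 samples, 1 male and 1 female, analysed as 1 pooled matrix. The WT matrix held 170663481 contacts and the H1 cTKO matrix 183315791. Without contacts inside a bin, the median per 100 kb bin was 10912 in WT and 12428 in H1 cTKO. There were no replicates among the matrices, so every error given below is counting error only. The targeted genes H1f2, H1f3 and H1f4 span 725, 776 and 782 bp, or 2.90% to 3.13% of a 25 kb bin, and their deletion could not be checked in these bins. Their 100 kb bins on chromosome 13 lay in the A compartment in both genotypes, with E1 of 1.18 in WT and 1.16 in H1 cTKO for H1f2, 1.02 and 0.930 for H1f3, and 1.05 and 1.03 for H1f4.

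To compare how contacts were spread over distance, cis contacts were counted in bands. H1 cTKO cells had fewer contacts at short range and more at 0.5 to 3 Mb. Contacts under 0.2 Mb made up 36.0% of cis contacts in WT and 31.6% in H1 cTKO, a ratio of 0.877 (counting interval 0.8768 to 0.8774), and the ratio was below 1 on 20 of 20 chromosomes (0.859 to 0.928). At 1 to 3 Mb the share was 7.16% in WT and 7.91% in H1 cTKO (ratio 1.105), higher on 20 of 20 chromosomes. The ratio was 1.096 at 0.5 to 1 Mb, 1.06 at 3 to 10 Mb, 1.04 at 10 to 30 Mb, 1.09 at 30 to 100 Mb and 1.16 beyond 100 Mb. At 0.2 to 0.5 Mb it was 1.02. These ratios depend on the total, since a deficit in one band raises the share of the others. With contacts under 0.2 Mb left out of the total, the ratio fell below 1 at 0.2 to 0.5 Mb (0.958), 3 to 10 Mb (0.990) and 10 to 30 Mb (0.973), and it was 1.025 at 0.5 to 1 Mb, 1.033 at 1 to 3 Mb, 1.016 at 30 to 100 Mb and 1.09 beyond. Cis contacts made up 79.3% of all contacts in both genotypes (Wilson intervals 79.28% to 79.30% and 79.31% to 79.32%). Without contacts inside a 100 kb bin the shares were 73.9% in WT and 74.8% in H1 cTKO.

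**Figure D1:**
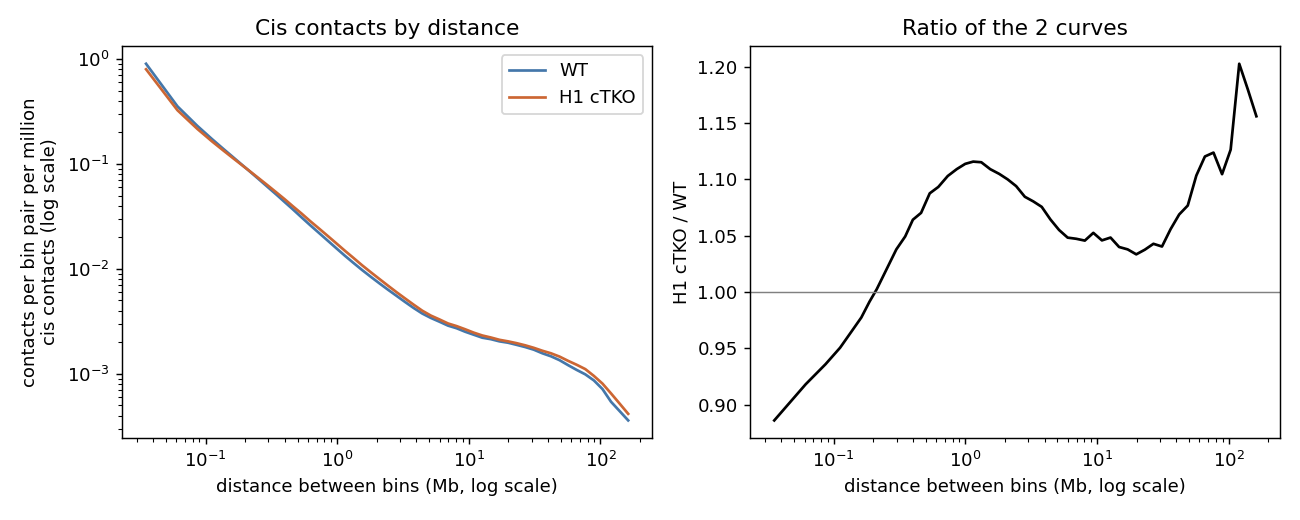
Left, contacts per pair of 25 kb bins (ppm of cis contacts) against distance (both axes log scale) in WT and H1 cTKO; right, the ratio of H1 cTKO to WT (linear axis) against distance. The ratio lies below 1 at the shortest distances, where the share under 0.2 Mb was 31.6% against 36.0%, and above 1 at 1 to 3 Mb, where it was 1.105.

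To ask which chromatin changed compartment, E1 was compared bin by bin. More of the genome moved from the inactive B to the active A compartment in H1 cTKO than the other way. Of 25048 bins, 1069 (4.27%) switched from B to A and 413 (1.65%) from A to B, and the A compartment went from 48.6% of bins in WT to 51.3% in H1 cTKO. B-to-A bins outnumbered A-to-B bins on 19 of 20 chromosomes, the exception being chromosome 17 (23 against 26), and the A share changed most on chromosome 14 (84 against 7). A random split of the WT contacts into equal parts gave 2 bins one way and 1 the other under the same rule, and a split of the H1 cTKO contacts gave 3 and 2. Which bins were called depended more on the processing. Of the calls in both directions, 1458 recurred after thinning, 1206 with 5% of bins removed, 1128 after quantile normalization and 945 without balancing. After quantile normalization, 715 bins switched from B to A and 709 from A to B. That setting makes the E1 distributions of the genotypes equal, and with them the A share (49.7% in both). Near-equal counts then follow by construction, so it cannot test the balance between the directions. In every other setting tried B-to-A bins outnumbered A-to-B bins, for example 939 against 492 with the correlation matrix. By more than 3 counting SDs, E1 was lower in H1 cTKO in 9539 bins and higher in 7469. Across bins, which are not independent replicates, Pearson's r between the genotypes was 0.952, against 0.9985 between the parts of the WT split.

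Switched bins formed 230 B-to-A regions, the longest of 1300 kb, and 62 A-to-B regions. B-to-A bins held 478 protein-coding genes, or 0.447 per bin, and A-to-B bins 204, or 0.494 per bin, against 0.860 in bins that did not switch. Decile 5 of mean E1 had 0.448 per bin. Among the 10 regions with the largest E1 rise were 3 on chromosome 18. One held Dsg1c (20100001 to 20300000; E1 from -1.49 in WT to 0.058 in H1 cTKO) and another Dsg2, Dsg3 and Dsg4 (20400001 to 20600000; -0.971 to 0.460). These genes encode desmogleins, adhesion proteins of epithelial cell junctions. The third held 4930426D05Rik, Garem1 and Klhl14 (21200001 to 21800000; -1.005 to 0.434). The largest rise was at Lrig3 on chromosome 10 (125900001 to 126100000; -1.39 to 0.161, difference 1.55 with a counting SD of 0.020). Ptprg, a receptor tyrosine phosphatase gene, went from -1.33 to 0.143 over 500 kb of chromosome 14 (11500001 to 12000000). The neuronal RNA-binding protein gene Elavl4 on chromosome 4 (110200001 to 110400000) went from -1.24 to 0.135, and Adamtsl1 on the same chromosome (85400001 to 86000000) from -1.13 to 0.183. Adamts9 and Prickle2 shared a region of 900 kb on chromosome 6 (92300001 to 93200000; -1.08 to 0.211), and a region with no protein-coding gene lay nearby (93600001 to 93800000; -1.31 to 0.061).

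Among regions that moved from A to B, the largest fall was in a region of chromosome 7 with no protein-coding gene (125000001 to 125300000; E1 from 0.383 to -0.501). Prdm16, a stem cell transcription factor gene, went from 0.745 to -0.039 on chromosome 4 (154400001 to 154600000). Also on chromosome 4, Igsf21 (140000001 to 140200000) went from 0.152 to -0.533 and the glutamate receptor gene Grik3 (125600001 to 125900000) from 0.147 to -0.511. Vav3 went from 0.354 to -0.254 on chromosome 3 (109500001 to 109700000), Mdfic from 0.265 to -0.365 on chromosome 6 (15600001 to 15900000), and Adck1 with Gm10264 from 0.465 to -0.139 on chromosome 12 (88300001 to 88500000). The other 3 of the 10 regions, on chromosomes 6, 4 and X, held no protein-coding gene. The largest falls were smaller than the largest rises, with a mean difference of -0.884 against 1.55.

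**Figure D2:**
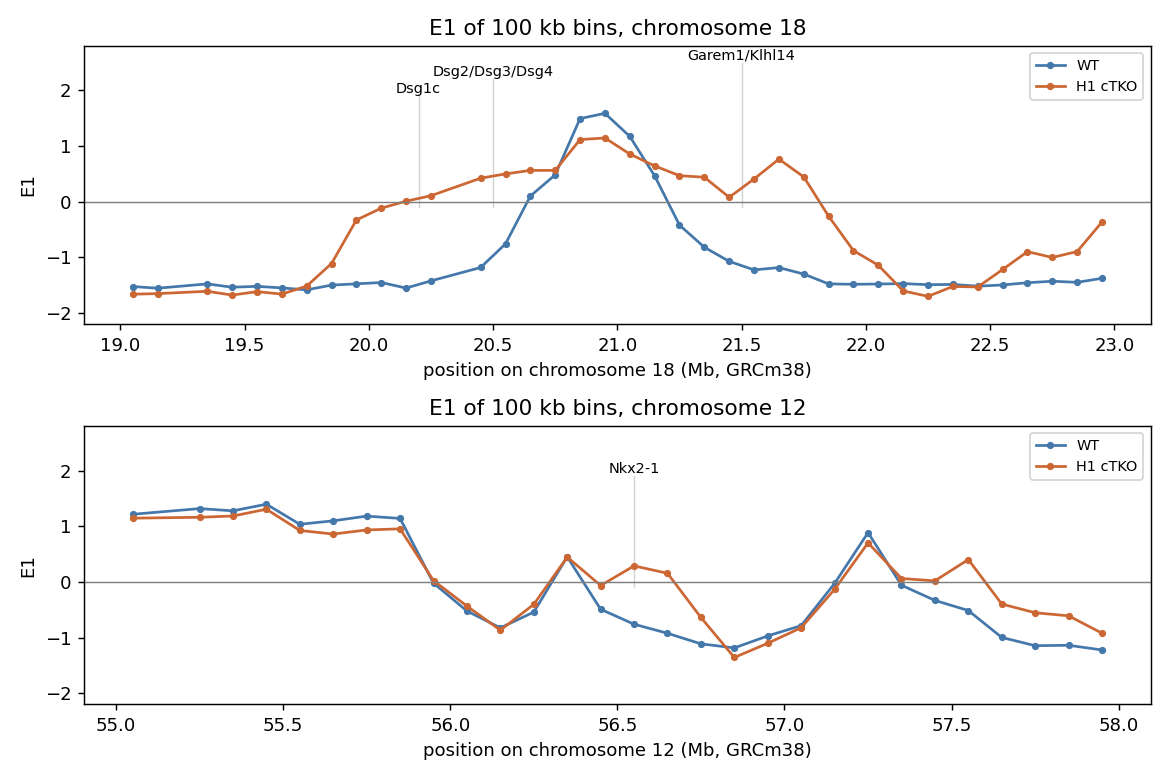
E1 of 100 kb bins in WT and H1 cTKO against position (Mb, GRCm38) on parts of chromosome 18, with the 3 named regions marked, and of chromosome 12, with Nkx2-1 marked; values above 0 are compartment A. At Dsg2, Dsg3 and Dsg4 E1 was -0.971 in WT and 0.460 in H1 cTKO, and at Nkx2-1 it was -0.761 and 0.288.

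To ask whether the shift depended on the starting compartment, bins were split by decile of mean E1. Chromatin at the intermediate part of B shifted toward A, while the most B chromatin became more negative. The median E1 difference was 0.227 in decile 4 (counting SD 0.0042, above 0 on 19 of 20 chromosomes) and 0.180 in decile 5 (20 of 20). It was -0.255 in decile 1 (below 0 on 20 of 20 chromosomes), -0.104 in decile 2 and -0.071 in decile 10. Deciles 7 to 9 lay between -0.028 and -0.052. Because E1 is scaled per chromosome, these are changes in the shape of its distribution. After quantile normalization, which removes differences in that shape by construction, every decile lay between -0.034 and 0.0058, with decile 4 at -0.020 and decile 5 at -0.030. Decile 4 was at 0.130 and decile 1 at -0.107 with deciles of WT E1, and at 0.108 and -0.185 without balancing, and with the correlation matrix decile 1 was at -0.0559 and deciles 8 to 10 were at 0.0325, 0.0449 and 0.0453.

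**Figure D3:**
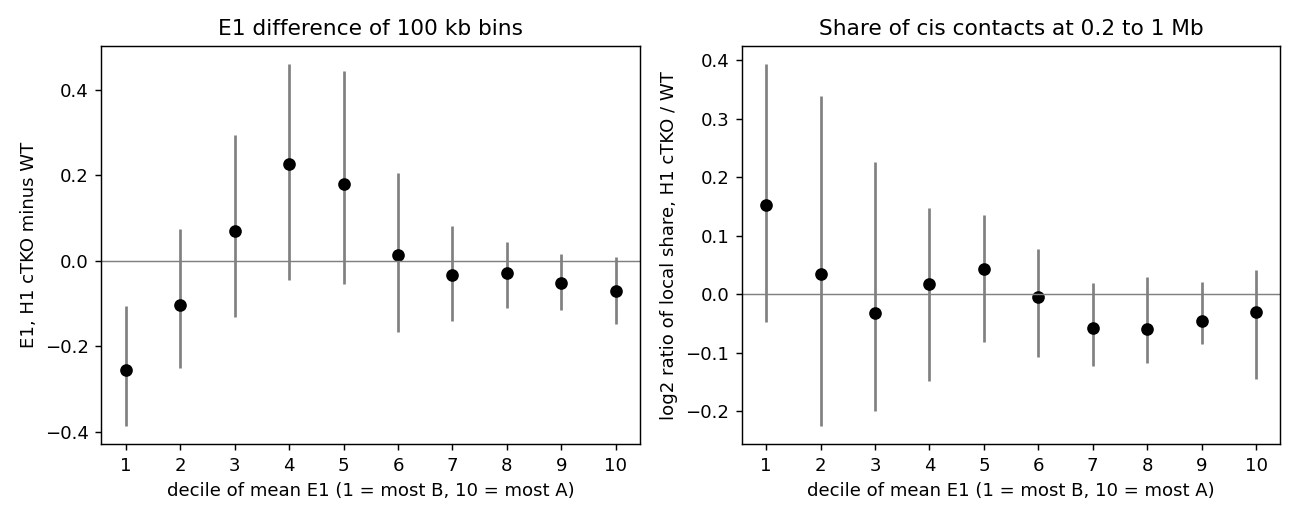
Left, median E1 difference (H1 cTKO minus WT, points) with quartiles (bars) by decile of mean E1; right, median log2 ratio (H1 cTKO over WT) of the share of cis contacts at 0.2 to 1 Mb, with the range of chromosome medians (bars). E1 was higher in H1 cTKO in decile 4 (0.227) and lower in decile 1 (-0.255), and the local share was higher in decile 1 (0.153).

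To compare how well A and B were kept apart, observed over expected contacts were averaged between classes of E1. The separation was weaker in H1 cTKO. Compartment strength in cis was 20.0016 in WT (counting SD 0.060) and 15.7 in H1 cTKO (0.041), a ratio of 0.784, and in trans 11.04 and 9.81 (ratio 0.888). The difference in trans was smaller without X, whose share of contacts differed between the pools. On autosomes the ratio was 0.799 in cis and 0.941 in trans. With the extreme 10% of E1 it was 0.902 and 0.966. Contacts between the extreme A and B classes increased from 0.119 to 0.147 of expected in cis and from 0.187 to 0.232 in trans. In cis, AA contacts were at 2.22 in WT and at 0.883 of that in H1 cTKO, and BB contacts went from 2.55 to 2.66. In trans both went up, AA from 2.57 to 2.801 and BB from 1.57 to 1.74. The largest relative change in cis was between the second lowest 20% of E1 and the highest 20%, from 0.210 to 0.314 (ratio 1.496). The first eigenvalue was lower in H1 cTKO on 20 of 20 chromosomes (ratios 0.787 to 0.945).

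Domain boundaries were compared at 25 kb. Their number was similar, with 4068 in WT and 4117 in H1 cTKO, and 2916 were shared (71.7% of WT boundaries). A pair of Poisson resamples of the WT matrix shared 80.5% of 4364 boundaries, so part of the difference was within counting noise. Resampling adds noise to that already in the matrix and gave more boundaries than the WT matrix. The 80.5% therefore need not be the share that repeat libraries would give. At shared boundaries the score was on median 0.030 higher in H1 cTKO, a weaker boundary (quartiles -0.114 and 0.211), with 1607 of 2916 weaker. This shift was small beside the median counting SD of the score difference (0.066). Median prominence at shared boundaries was close, at 1.016 in WT and 0.9996 in H1 cTKO. The insulation score correlated across bins between genotypes (r = 0.910) less than between the resamples (r = 0.990), and its SD was 0.601 in WT and 0.571 in H1 cTKO. Within 100 kb of a switched bin 67.1% of 660 WT boundaries were shared, against 72.6% of 3408 elsewhere.

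The share of local contacts, at 0.2 to 1 Mb, changed in opposite directions in the most B and in A bins. It rose in the most B bins, where it was lower in WT, and fell in deciles 7 to 10, so these came closer together. There was no single order in between. The share also depends on contacts over 1 Mb, and compaction was not measured. In decile 1 the local share was 17.0% in WT and 18.8% in H1 cTKO (median log2 ratio 0.15, above 0 on 19 of 20 chromosomes). In decile 8 it went from 27.1% to 25.9% (log2 ratio -0.060, below 0 on 18 of 20) and in decile 10 from 24.2% to 23.6% (-0.031, below 0 on 17). Decile 3, in B, was at -0.031 (below 0 on 10 of 20), decile 5 at 0.043 (above 0 on 16) and decile 6, in A, at -0.00505 (below 0 on 11), with a change of sign in 2 alternatives. Bins that switched from B to A had a median log2 ratio of 0.21 and bins that switched from A to B one of -0.12, against -0.013 in the rest. Among the named B-to-A regions the ratio ranged from -0.15 at Lrig3, the region with the largest E1 rise, to 1.19 at Dsg2, Dsg3 and Dsg4, with 0.70 at Dsg1c and 1.16 at Elavl4.

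To ask which kinds of genes lay in shifted chromatin, 20 gene lists were placed. Genes of developmental transcription factors, silent in mature T cells and often bound by Polycomb proteins, moved toward A as a list, mainly where they lay in B in WT. Their 57 bins had a median E1 difference of 0.272 (middle 95% of matched random lists -0.064 to 0.070). By more than 3 counting SDs, 39 bins were higher, 12 lower and 6 neither, and 17 switched from B to A with 0 switching back. In WT 30 of the bins were already in A, and in H1 cTKO 47 were. Of the bins in B in WT only that of Irx1 was lower in H1 cTKO, while bins in A in WT went both ways. The 28 bins of the list with the higher coverage had a median of 0.0903 and the others one of 0.493. In the same list Nkx2-1, a regulator of lung and thyroid development, went from -0.761 to 0.288 and Gsc, of the early organizer, from -0.317 to 0.650. Gata5 (1.46 to 0.880) and Irx1 (-1.63 to -1.97) had the largest falls. With the mean over all bins of each gene the list's median was 0.232, and its percentile among circularly shifted lists was 100.

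T cell identity genes also stood above matched lists, with a median difference of 0.023 against -0.097 to 0.000586. Of their 28 bins, all in A in both genotypes, 10 were higher by more than 3 counting SDs, 4 lower and 14 neither. Lck, the kinase that starts T cell receptor signalling, had E1 of 0.911 in WT and 1.17 in H1 cTKO, and Gata3, a T cell transcription factor, 0.585 and 0.817. Cd247 had the largest fall (1.22 and 1.08). The list lay at percentile 99.8 of matched lists but 85.5 of circularly shifted ones. CD8 effector and activation genes had a median difference of -0.016 (percentile 84.6), with 8 of 37 bins higher, 9 lower and 20 neither, and no switch. Cd44, an activation marker (0.725 and 1.09), and the interleukin 2 receptor gene Il2ra (0.845 and 1.13) had the largest rises. Klrg1 (0.544 and 0.290) and Gzmb, which encodes granzyme B (1.12 and 0.988), had the largest falls.

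**Figure D4:**
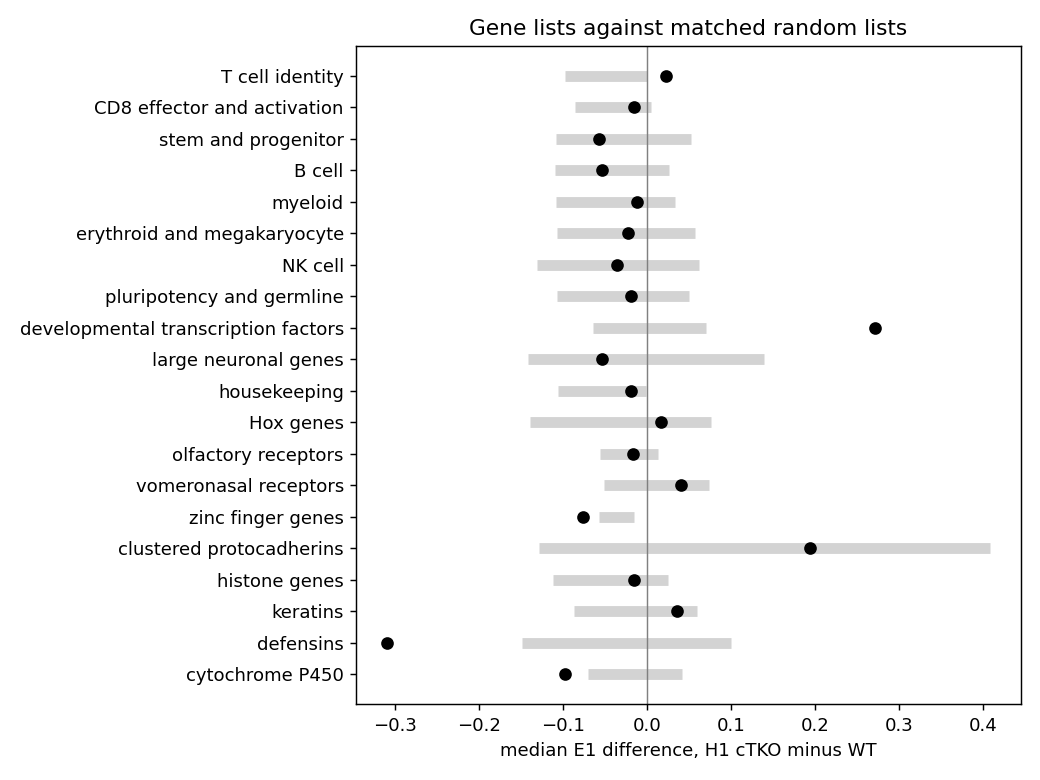
Median E1 difference (H1 cTKO minus WT, points) of the bins of 20 gene lists, with the middle 95% of matched random lists (grey bars). Developmental transcription factors (0.272) and T cell identity genes (0.023) lie above their bars, and zinc finger genes (-0.076), defensins (-0.310) and cytochrome P450 genes (-0.098) below.

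Lists of other blood cells did not stand apart from matched lists. Stem and progenitor genes had a median difference of -0.057 (percentile 25.4). In that list Meis1 (-1.39 to -0.548) and Mecom (-0.888 to -0.413), both stem cell transcription factors, had the largest rises, and Prdm16 (0.720 to -0.061) and Tal1 (1.00 to 0.743) the largest falls. B cell genes were at -0.053 (percentile 38.7). There Blk was higher by 0.206, while Blnk went from 0.489 to 0.065 and Cd72 from 1.89 to 1.55. Myeloid genes were at -0.012 (percentile 74.8), with Mrc1 going from -0.127 to 0.158, Cebpa from 0.417 to 0.580, Adgre1 from -0.040 to -0.368 and Csf3r from 1.36 to 1.17. Erythroid and megakaryocyte genes were at -0.023 (percentile 57.3). Pf4 went from -0.523 to -0.152 and Hba-a2 from 0.677 to 0.778, while the carbonic anhydrase genes Car1 and Car2 went from -0.154 to -0.561 and from 0.446 to 0.061. NK cell genes were at -0.036 (percentile 52.9), with Cd160 higher by 0.203 and Fcgr3 and Gzmc lower, at 1.18 to 1.04 and 1.12 to 0.988. The second highest difference in that list, 0.012 at Klre1, was within 3 counting SDs (SD 0.019).

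Pluripotency and germline genes had a median of -0.019 (percentile 59.7), although Sox2, a pluripotency factor that also acts in neural development, switched from B to A (-0.590 to 0.511). Lin28b went from -0.453 to -0.00515, Nanog from 1.20 to 0.929 and Dppa3 from 0.788 to 0.533. Large neuronal genes, all in B in WT, had a median of -0.053 (percentile 23.96). Thsd7b (-0.864 to 0.304) had the largest rise and Fgf14 (-0.611 to -1.39) and Cntn5 (-1.22 to -1.82) the largest falls. Housekeeping genes stayed in A in all 25 bins, at -0.019 (percentile 90.5). Eef1a1 (1.103 to 1.295) was higher, and so was Ywhaz in its midpoint bin (1.03 to 1.11) but not over its whole body (difference -0.012), and Gusb (1.22 to 0.918) and Rpl7 (0.962 to 0.707) lower.

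Among gene families defined by symbol, 3 lay below matched lists. Zinc finger genes had a median difference of -0.076 over 294 bins, with 141 bins lower, 46 higher and 107 neither, and 14 A-to-B against 4 B-to-A switches. Zfp169 switched from A to B (0.338 to -0.335) and Zfp385b had the largest rise (-1.22 to -0.300). Defensin genes were at -0.310 over 14 bins, of which 12 were lower and 0 higher, with the largest fall at Defb50 (-0.847 to -1.59) and the smallest difference at Defb22 (1.099 and 1.052, within 3 counting SDs). Cytochrome P450 genes were at -0.098 over 72 bins, with 40 lower and 12 higher. Cyp19a1, the aromatase gene, went from -1.04 to -0.084 and Cyp2c50 from -0.646 to -1.46. Chance would give 0.50 lists above and 0.50 below the middle 95% of matched lists if bins were independent. Matched lists draw scattered bins, while genes of several of these families lie in clusters of neighbouring bins. Against circularly shifted lists, which keep the clusters, 1 list lay above the middle 95% and 2 below. The cytochrome P450 list was at percentile 3.75 among circularly shifted lists. Clustered protocadherins were at 0.194 (percentile 75.4), with the largest rise at Pcdhb2 (-1.01 to -0.245) and the largest fall at Pcdhb20 (-0.369 to -0.541). Hox genes were at 0.017 (percentile 80.5; Hoxd1 0.377 to 0.662, Hoxa5 1.03 to 0.920), and vomeronasal receptors at 0.040 (82.4; Vmn2r3 -1.21 to -0.058, Vmn2r17 -0.593 to -1.20). Olfactory receptors were at -0.017 (55.7; Olfr1261 -1.37 to -0.324, Olfr785 -1.41 to -2.13), and keratin and keratin-associated genes at 0.036 (90.9; Krtap27-1 -1.05 to -0.736, Krtap20-2 -1.32 to -2.23). Histone genes were at -0.016 (79.1; H2bc18 0.636 to 0.794, H4f16 1.51 to 1.32).

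Local contacts were compared for the same lists. Clustered protocadherins had a median log2 ratio of local contacts of 0.60 (matched median 0.02), keratins 0.25, NK cell genes 0.13, olfactory receptors 0.11 and cytochrome P450 genes 0.11, each at percentile 99.5 or higher of matched lists. Matched lists draw scattered bins, while these genes lie in clusters of neighbouring bins that are not independent (8 bins for the protocadherins). Circular shifts were not applied to local contacts. CD8 effector and activation genes were at 0.02 (percentile 97.7). Large neuronal genes were at -0.05 against a matched median of 0.09 (percentile 0.140), and erythroid and megakaryocyte genes at -0.11 (percentile 2.42).

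The antigen receptor loci, whose segments are cut out during rearrangement, were examined as a check of the sorted cells. The Tcrd interval, which lies inside Tcra and is removed when Tcra rearranges, had far less coverage in H1 cTKO than in WT. Over chromosome 14 from 53946073 to 54159198, coverage was 0.197 of the chromosome median in WT (5508 contact ends) and 0.042 in H1 cTKO (1372), a ratio of 0.214 (0.201 to 0.227). The flanking 500 kb on each side were at 0.748 and 0.597, but the flank before the interval is Trav DNA inside Tcra that rearrangement also deletes. The first bin past Tcra (54225001 to 54250000) was at 1.23 in WT and 1.08 in H1 cTKO. The whole Tcra locus (52427967 to 54224198) was at 0.351 and 0.265, and its Traj segments at 0.688 and 0.461. Tcrg on chromosome 13 (19178042 to 19356476) was at 0.740 and 0.366, a ratio of 0.495 (0.483 to 0.507). Tcrb on chromosome 6 (40891296 to 41558371) differed little, at 0.544 and 0.517. Among immunoglobulin loci, Igh was at 0.839 and 0.796, Igk at 0.682 and 0.703, and Igl at 0.766 and 0.795. Mean E1 at Igk went from -0.846 to -0.434 and at Igl from -0.914 to -0.202, while at Igh it was 0.675 and 0.648.

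**Figure D5:**
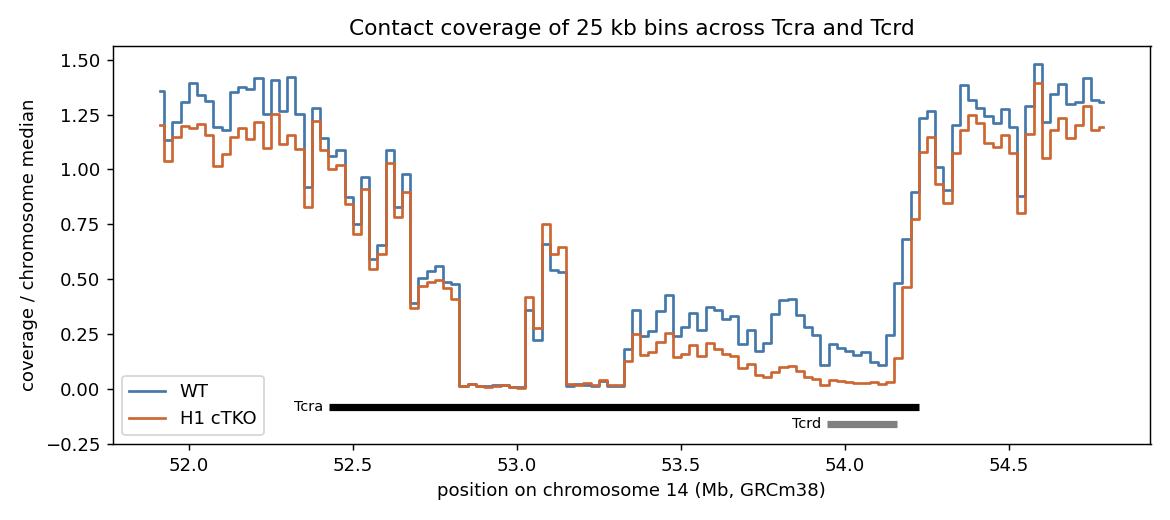
Coverage of 25 kb bins relative to the chromosome median across Tcra and Tcrd on chromosome 14 (Mb, GRCm38) in WT and H1 cTKO, with both loci drawn as bars below. Over Tcrd the WT line lies above the H1 cTKO line, with means of 0.197 and 0.042.

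The X chromosome had a larger share of contact ends in H1 cTKO (3.30% in WT, 3.83% in H1 cTKO, ratio 1.16) and the Y a smaller one (ratio 0.680, 0.674 to 0.686). Autosome ratios lay between 0.956 and 1.02. Among trans contacts alone, X had a ratio of 1.098, within the range of the autosomes (0.867 to 1.133), and Y one of 0.709. With 1 male and 1 female sample in each genotype, the ratios over all contacts correspond to 30.3% of contacts from the female in WT and 52.2% in H1 cTKO, if X and Y contacts scale with copy number relative to the autosome median, and those over trans contacts to 39.2% and 56.0%. Without X, 959 bins switched from B to A and 395 from A to B.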

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

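The tests of the neighbourhood, of B cells, of unrearranged alleles as the whole cause, of unligated pairs and of the autosomes were chosen after the values had been seen, and the set of other gene families was corrected after its values had been seen.

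Contacts inside the mitochondrial genome, which no comparison used, were more frequent in H1 cTKO, at 22.75 ppm of contacts (Wilson interval 22.07 to 23.45) against 17.22 in WT (16.61 to 17.86). Contacts between mitochondrial and nuclear DNA were at 54.3 ppm in H1 cTKO and 52.7 ppm in WT.

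The first pattern weighed is the lower coverage of the Tcrd interval in H1 cTKO. A general loss of contacts in the neighbourhood does not account for it, because coverage over the flanks was still 0.266 of the WT value. The flank on the Trav side is itself partly deleted, so this value mixes deleted and intact DNA. The Ighd and Ighj segments, which B cells delete, gave no sign of more B cells in the WT pool. Their coverage over flanks had a ratio of 0.9989. The ratio that a small share of B cells would give was not worked out, so B cells are not excluded. The Tcrd DNA in WT made few contacts with the rest of chromosome 14 for its contacts with other chromosomes, with a quotient of 0.199 (0.175 to 0.227) of that in the flank, and in H1 cTKO 0.3675. More unrearranged alleles in WT are argued against as the whole cause by the ratio of these values, 0.542 (0.424 to 0.691), because DNA still on the chromosome would have raised the quotient in WT. As a part of the cause they stay open. Trav-to-Traj contacts, set to decide this by a ratio of H1 cTKO to WT over 1, had 0.626 (0.512 to 0.767), but this limit took no account of the Trav DNA lost near Traj, which alone gives an expected ratio of 0.593, inside the interval. A candidate explanation is that part of this DNA lay on the circles that rearrangement excises, which are not copied at division, and that the pools differed in how far their cells had divided, which was not tested.

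The second pattern is the higher E1 at developmental transcription factor genes. The difference in total contacts is argued against by matrices thinned to equal totals, which does not equalise the contacts per bin and left the list at percentile 100 (median 0.275), and the choice of genes by 121 other genes of such families in 115 further bins, also at percentile 100 with a median of 0.072. Coverage is not settled, since the 28 better covered bins of the list had a median of 0.0903 and the others 0.493. A different mix of cells cannot be told apart from the genotype, since only 26.6% of the WT Tcrd coverage over flanks was left in H1 cTKO and bulk matrices do not separate cells. Loss of H1 stays open as the biological explanation.

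The third pattern is the deficit of contacts under 200 kb. Fewer unligated or self-ligated pairs cannot be the whole cause if these lie within 25 kb, because among contacts between different 25 kb bins the share at 50 to 100 kb still had a ratio of 0.896 (0.895 to 0.897). The unequal share of X is argued against by the autosomes (0.878), and a loss from 1 compartment by the deciles of E1, where the highest ratio was 0.921. Differences in crosslinking or digestion between the libraries were not tested, and loss of H1 stays open.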

How the results depend on the processing

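The alternatives that used a total without contacts under 200 kb, an E1 difference over 0.5, deciles from a random part of WT, strength classes from the mean E1, a diamond without distant pairs and gene-body means were chosen after seeing the data. Of 244 values recomputed for 47 results, 104 stayed within the counting interval (or within 1.5 times, for counts), 122 moved beyond it in the same direction and 18 changed direction. Apart from quantile normalization, which equalises the E1 distributions by construction, the cause was not tested. No paired analysis was possible because the pooled matrices carry no replicate, and leaving out a replicate was not possible because there is 1 pooled matrix per genotype.

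The median E1 differences of deciles 1 to 10 were, after quantile normalization, -0.02741, -0.03335, -0.03362, -0.01963, -0.03026, -0.02532, -0.005115, 0.005843, -0.002602 and -0.00308. With the correlation matrix they were -0.05594, -0.03975, 0.02153, 0.1436, 0.1383, 0.001712, -0.0305, 0.03249, 0.04493 and 0.04526. Scaled by the square root of the eigenvalue they were -0.1563, -0.02677, 0.1242, 0.2604, 0.1921, -0.0005334, -0.06452, -0.06932, -0.0996 and -0.1439. Without balancing they were -0.1849, -0.1317, -0.02743, 0.1077, 0.1779, 0.04012, 0.01055, -0.01613, -0.05353 and -0.1091. With 5% of bins removed they were -0.2473, -0.06695, 0.07934, 0.1996, 0.125, -0.0233, -0.04715, -0.0262, -0.04482 and -0.06156, and in 200 kb bins -0.2703, -0.09262, 0.09729, 0.2314, 0.1538, 0.01701, -0.0365, -0.03055, -0.05631 and -0.07611. On autosomes they were -0.2583, -0.1186, 0.08162, 0.2453, 0.1795, 0.00111, -0.03623, -0.02846, -0.05095 and -0.06891. With deciles of WT E1 they were -0.107, -0.058, -0.001128, 0.1301, 0.1427, 0.01492, -0.02759, -0.03056, -0.05562 and -0.09844, and with deciles from a random part of WT -0.1151, -0.05954, 0.009272, 0.1243, 0.1407, 0.01473, -0.02813, -0.02902, -0.05654 and -0.09902. Decile 1 was negative in all 10 alternatives, decile 4 positive in 9 and decile 5 positive in 9.

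The log2 ratios of local contacts of deciles 1 to 10 were, up to 3 Mb, 0.1212, 0.03312, -0.008632, 0.01411, 0.03453, 0.01162, -0.03038, -0.03763, -0.0238 and -0.01353. With balanced counts they were 0.1748, 0.05452, -0.03474, 0.01548, 0.04781, -0.0004573, -0.05065, -0.05793, -0.04683 and -0.03668. As a share of all contacts of the bin they were 0.1807, 0.0589, -0.002667, 0.04892, 0.08537, 0.0326, -0.02694, -0.03222, -0.03287 and -0.02881.

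For distance, the ratio on autosomes was 0.878 under 0.2 Mb, 1.03 at 0.2 to 0.5, 1.098 at 0.5 to 1, 1.06 at 3 to 10, 1.04 at 10 to 30 and 1.15 beyond 100 Mb. As a share of all contacts it was 0.877 under 0.2 Mb. With the 25 kb matrix it was 0.882 under 0.2 Mb, 1.04 at 0.2 to 0.5 and 1.1 at 0.5 to 1 Mb. As a share of cis contacts over 200 kb it was 0.958 at 0.2 to 0.5, 1.025 at 0.5 to 1, 1.033 at 1 to 3, 0.990 at 3 to 10, 0.973 at 10 to 30, 1.016 at 30 to 100 and 1.09 beyond 100 Mb. Without contacts inside a 100 kb bin the cis share differed by 0.969 percentage points, and among trans contacts the ratio was 1.098 for X and 0.709 for Y.

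Switching from A to B was 2.83% of bins after quantile normalization. With an E1 difference over 0.5, 2.19% of bins went from B to A and 0.355% from A to B. Compartment strength was lower in H1 cTKO in all settings tried. Its ratio in cis and trans was 0.799 and 0.941 on autosomes, 0.750 and 0.865 with 5% of bins removed, 0.743 and 0.829 without balancing, 0.758 and 0.870 in 200 kb bins, 0.902 and 0.966 with the extreme 10%, and 0.705 and 0.768 with classes from the mean E1. A 500 kb window gave 2671 boundaries in WT and 2743 in H1 cTKO, and 44.2% were shared in the same bin. Without pairs over 250 kb apart there were 5035 and 5103, with 73.1% shared. Against circularly shifted lists 1 list lay above the middle 95%. In 100 kb bins the coverage ratio was 0.772 for Tcra, 0.318 for Tcrd, 0.681 for Tcrg, 0.956 for Igh and 1.04 for Igk.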

Other observations

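Beyond the fixed list, other genes of developmental transcription factor families had a median E1 difference of 0.072 (middle 95% of matched lists -0.058 to 0.016). Of 115 bins holding 121 such genes, 58 were higher in H1 cTKO by more than 3 counting SDs, 33 lower and 24 neither, and 13 switched from B to A and 2 from A to B. Chosen after their values were seen, Prrx1, a limb mesenchyme factor, went from -0.255 to 0.895, and Lhx8, a forebrain factor, from -0.604 to 0.453. Zic1 and Zic4, neighbours in 1 bin of chromosome 9, went from -1.48 to -0.323. Sox5 had the largest fall, from 0.526 to -0.024.

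Total coverage shifted between compartments as well. The median log2 ratio of coverage (H1 cTKO over WT) was 0.11 in deciles 3 and 4 of E1, -0.056 in decile 1 and -0.075 in decile 10. Across bins, which are not independent, its Spearman correlation with mean E1 was -0.313. The short-range deficit was deepest in decile 3, where contacts under 200 kb made up 32.6% of cis contact ends in WT and 27.6% in H1 cTKO, a ratio of 0.846.

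Contacts between chromosome ends in trans differed little. Ends on the centromere side contacted each other at 2.25 times the trans mean in WT and 2.16 in H1 cTKO, the other ends at 2.39 and 2.36, and opposite ends at 1.54 and 1.46. Among boundaries outside X, the one that weakened most lay inside Tcra on chromosome 14 (53725001 to 53750000), with a score of -1.18 in WT and 1.12 in H1 cTKO. This bin had a coverage of 0.173 of the chromosome median in WT and 0.064 in H1 cTKO, in DNA that rearrangement deletes, so the score there is not one of intact DNA. Boundaries that strengthened most included those at Pik3c2g on chromosome 6 (-0.23 to -1.62), Robo1 on chromosome 16 (-0.10 to -1.18) and Serpina1e on chromosome 12 (-0.71 to -1.76).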
